A study of Canis lupus familiaris with 5 samples.

How the data were processed

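RNA from 5 samples was hybridised to canine Affymetrix expression arrays, 1 array per sample. Of the samples, 3 were leukocyte pellets from EDTA blood of healthy female dogs, in which red cells had been lysed for 30 minutes, and 2 were the mammary carcinoma lines CMM115 and CMM26. The lines were grown to confluence at 37 °C in medium with 10% serum and harvested with trypsin, per the labels' protocols. From 2 µg of RNA each, biotin-labelled material was made with the One Cycle protocol, per the labels.

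The deposited values are log2 expression values that the authors made with RMA in Partek, per the submitters' processing notes. The versions and settings of RMA and Partek are not given in the sources used here. That the values are log2 was inferred from the use of RMA and from their range. The shared distribution was checked on the values: the sorted values of each array deviated from their mean over the arrays by at most 0.105. Of 43035 probe sets, 111 control probe sets were set aside and 42924 were tested, with 0 missing values. The table carries no detection calls, so no probe set could be called absent, and low values may include background only. Identical values on at least 2 arrays occurred in 16809 probe sets (39.2%), whose median level was 4.69 against 6.89 for the others, and 308 had the identical value on all 5 arrays. Scan dates were not used here.

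Gene symbols came from the annotation of the array platform. A single symbol was given for 29254 of the tested probe sets, several for 439 and none for 13231, which are unnamed here. Of those with a single symbol, 27680 were matched by gene identifier to the RefSeq gene table of the assembly UU_Cfam_GSD_1.0, which was used for names only and changed 0 symbols. A gene was represented by its probe set with the highest mean over the 5 arrays, which gave 15115 genes, 8254 of them with more than 1 probe set. Among the genes named for the comparison of lines with blood, 0 had another probe set past the threshold in the opposite direction. Of 70 such genes that passed and had more than 1 probe set, 46 had all of them past the threshold in the same direction, and 4 genes that did not pass had another probe set that did.

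Lines and blood were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 residual and 1.24 prior degrees of freedom), two-sided. P-values were adjusted by Benjamini-Hochberg over the 42924 probe sets, and an adjusted p under 0.05 was called. The lines entered as 1 group of 2 arrays, so the error pools the difference between the lines with the spread of the donors. Where the lines differ more than the donors, the SE and the p-value can be too small. The gene F3, for example, had an SD of 2.22 in the lines and 0.21 in blood, with an SE of 1.00. Probe sets with identical values have variances near 0, of which limma warned. The gap of a gene is the lower line minus the highest donor, or the lowest donor minus the higher line, and 8-fold was the bound for counting gaps. Chance gives no overlap between groups in 20% of probe sets, from the 10 splits of 5 arrays into groups of 3 and 2.

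Before the data were examined, the tests, the alternatives, the rule for named genes and 26 gene lists were fixed. The lists cover the 6 candidate markers put forward by the study, which were recalled from its published work and not checked against it, and epithelial, mammary, stromal, proliferation, metabolic, leukocyte, platelet, erythroid, endothelial, interferon and inflammatory genes. List members without a named probe set, such as MKI67, KRT5 and the globin genes, were not measured here. The result of 1 of the 26 lists is not reported here. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The alternatives were camera with an estimated correlation, under which 0 lists were called, and fry, which asks whether the genes of a list move one way on balance. Fry called 9 lists higher and 11 lower. With an estimated correlation the call was lost even for the endothelial list, whose estimate of 0.01 equals the preset. The receptor tyrosine kinase list lost its call too, with an estimate of -0.02. The size of the correlation alone therefore does not account for the lost calls.

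The named genes are the 12 with the widest gap in each direction among those past the threshold, all candidate markers, and from each other list up to 4 members past the threshold with the largest differences and up to 2 members that did not pass or went against the majority. Between the lines they are the 10 genes with the largest difference each way, if the higher value exceeded the median of all probe sets, and up to 3 members of each list outside the random range. Among donors they are the 8 genes with the widest range and up to 3 members per list with a range of at least 2 log2 units. Genes named beyond this rule are stated where they appear.

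The lines were compared with each other, and the donors among themselves, without a test. List medians between the lines were set against 10000 random lists of equal size matched over 20 bins of mean expression, with the 2.5th and 97.5th percentiles as bounds. These percentiles describe the 2 arrays. The random genes were drawn independently, so the bounds can be too narrow for lists whose genes move together. The estimated correlation was 0.68 in the MHC class II list and 0.65 in the interferon list.

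The alternatives left out each array in turn, left out the 25% of probe sets with the lowest mean, used an intensity trend with a robust prior, centred each array on its median or on ribosomal proteins, applied quantile normalization, took each line as its own group, required at least 2-fold, used treat against 2-fold, or averaged the probe sets of a gene. Where a line was left out, the lone line was assumed to vary like the donors, and so was each line where each was its own group. Gap counts were repeated at 4-fold and 16-fold, and pair counts at 4-fold. After the data had been seen, counts of list members without each array and the scaling of the line differences were added.

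The limma step was tested on simulated data for the comparison of lines with blood over 42924 probe sets. Of 50 changed probe sets per size, 18% were called at 2-fold, 72% at 4-fold, 100% at 16-fold and 96% at 64-fold, with 8 unchanged probe sets called. With 10731 probe sets changed 16-fold, 99.5% were called along with 481 unchanged ones. In 26 simulated lists of 20 genes among 15047, the 1 shifted list was called by camera with both correlations and 0 of the unchanged lists were called with the preset one. The simulated genes were independent of each other, whereas the estimated correlation was 0.71 in the cytotoxic and NK list and 0.67 in the cell cycle list. The simulation therefore does not show how often the preset correlation gives false calls on such lists. It also gave lines and donors the same spread, whereas DLA-DRA had an SD of 4.90 in the lines and 0.03 in blood. For genes on which the lines differ more than the donors, the simulated rates of right and false calls may not hold. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 served for tables and plots.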

Results

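Gene expression was measured on 5 arrays, 1 per RNA sample. Of these, 3 came from white blood cell pellets of 3 healthy female dogs without tumours, called donors 1, 2 and 3 here. The other 2 came from CMM115 and CMM26, established cell lines grown from canine mammary carcinomas, with 1 array each. The deposited values are log2 expression values of 43035 probe sets, of which 42924 were tested after the control probe sets were set aside. At each rank, the sorted values of every array lay within 0.105 log2 units of their mean over the arrays, a shared scale set by the normalization before deposit. The number of arrays limits the precision of every value below. The spread within the line group is a spread between different lines, because neither line had a second culture on an array.

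Across the tested probe sets, which are not independent replicates, Pearson's r was 0.985 between donors 1 and 2, 0.991 between donors 1 and 3 and 0.976 between donors 2 and 3. It was 0.959 between the lines and lay between 0.826 and 0.852 for the pairs of a line with a donor. The added poly-A control transcripts averaged 9.29, 10.09 and 8.60 in donors 1, 2 and 3, and 8.45 and 8.12 in CMM115 and CMM26 (log2, 24 probe sets). The 3′ probe set of beta-actin (ACTB) exceeded its 5′ probe set by 1.33, 1.64 and 1.37 log2 units in the donors, by 0.43 in CMM115 and by 2.10 in CMM26. Against another 5′ probe set of the gene the excess was 2.02, 1.57 and 2.28 in the donors, 1.84 in CMM115 and 2.01 in CMM26. Both lines exceeded all donors in none of the 3 actin pairs, but in both GAPDH pairs (0.83 and 0.74 in CMM115 and CMM26 against 0.34 to 0.57, and 0.28 and 0.21 against 0.04 to 0.12) and in the pair of the elongation factor EF1A (9.56 and 10.35 against 7.46 to 8.65). What RNA quality contributes to the comparison of lines with blood was not tested.

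The first comparison, of the carcinoma lines with blood, asked which transcripts are abundant in mammary carcinoma cells and scarce in circulating leukocytes, so that they could serve to detect tumour cells in blood. Many epithelial genes were higher in the lines than in blood, and some but not all of them were low in the 3 donors. KRT8, a keratin of simple epithelia, was higher in the lines by 8.69 log2 units (SE 0.34), and the epithelial adhesion molecule EPCAM by 7.57 (SE 0.10). Blood was marked by leukocyte and platelet transcripts. LYZ, the lysozyme of monocytes and granulocytes, differed by -9.71 log2 units (lines minus blood), the platelet chemokine PPBP by -9.35 and CD3D, a chain of the T cell receptor complex, by -9.12. The lower level in such differences was not shown to lie above background, since no detection calls were used here, so they are differences of array values and not folds of transcript. For each of these 5 genes both lines lay on one side of all 3 donors, with limma adjusted p-values between 0.000198 and 0.00107.

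In total 4314 probe sets were higher and 3751 lower in the lines at an adjusted p under 0.05, so that 53.5% of the calls were higher. Centring the arrays on ribosomal protein genes, which shifted the lines against blood by 0.17 log2 units, gave 5862 higher and 3079 lower, or 65.6% higher. Counted by gene, 1798 were higher and 1478 lower among 15115. Lines and donors did not overlap for 47% of the probe sets, against 20% expected by chance. Leaving out a donor lowered the counts, to 1218 probe sets higher and 1120 lower without donor 1, 2832 and 2538 without donor 2, and 2192 and 2219 without donor 3. Fewer arrays also leave fewer residual degrees of freedom, but equally few for each donor left out. They therefore do not account for the lower counts without donor 1 than without donor 2 or 3. Without donor 1 the blood group was donors 2 and 3, the donor pair with the lowest correlation (0.976).

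The genes with the widest gap between the lower line and the highest donor were, after KRT8, the matricellular gene CCN1 (log2 difference 9.08, SE 0.61), the chaperone clusterin CLU (8.02, SE 0.24), EPCAM, the collagen chain COL5A2 (7.39, SE 0.16) and the growth factor receptor EGFR (7.39, SE 0.28). KRT7 (6.87), the glutamate transporter SLC1A1 (7.19), WWC1 (6.69), the glutathione peroxidase GPX2 (6.62), the caveolin CAV2 (7.71) and the adhesion molecule CADM1 (6.72) completed the 12 widest. EPCAM read 12.90 and 12.66 in the lines and 5.17, 5.22 and 5.24 in the donors. CLU was as even between the lines, at 13.88 in CMM115 and 13.80 in CMM26, whereas CAV2 read 9.77 and 12.50. Other probe sets of some of these genes differed far less: CCN1 by 2.01 (adjusted p = 0.234), EGFR by 1.92 (adjusted p = 0.0148), CAV2 by 2.10 (adjusted p = 0.164) and CADM1 by as little as -0.14, with 3 of its 7 past the threshold. A gap of at least 8-fold separated 184 genes that were higher in both lines and 259 that were higher in all donors.

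In the other direction the widest gaps belonged to LYZ (log2 difference -9.71, SE 0.14), PPBP (-9.35, SE 0.10), CD3D (-9.12, SE 0.18) and S100A9, a calcium-binding protein of neutrophils (-9.14, SE 0.35). The protein kinase C gene PRKCB (-8.96), PLBD1 (-8.47), the lymphocyte surface protein CD48 (-8.18), the RNA-binding protein gene CELF2 (-8.13) and the protease inhibitor gene SERPINA1 (-8.22) followed, and then RGS18 (-8.38), the Fc receptor FCGR1A (-8.04) and EMB (-8.27). Other probe sets of PPBP (-3.36, adjusted p = 0.0832) and CELF2 (up to 0.04, with 2 of 6 past the threshold) differed less. CD48 read 4.18 in both lines and between 12.29 and 12.46 in the donors.

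**Figure D1:**
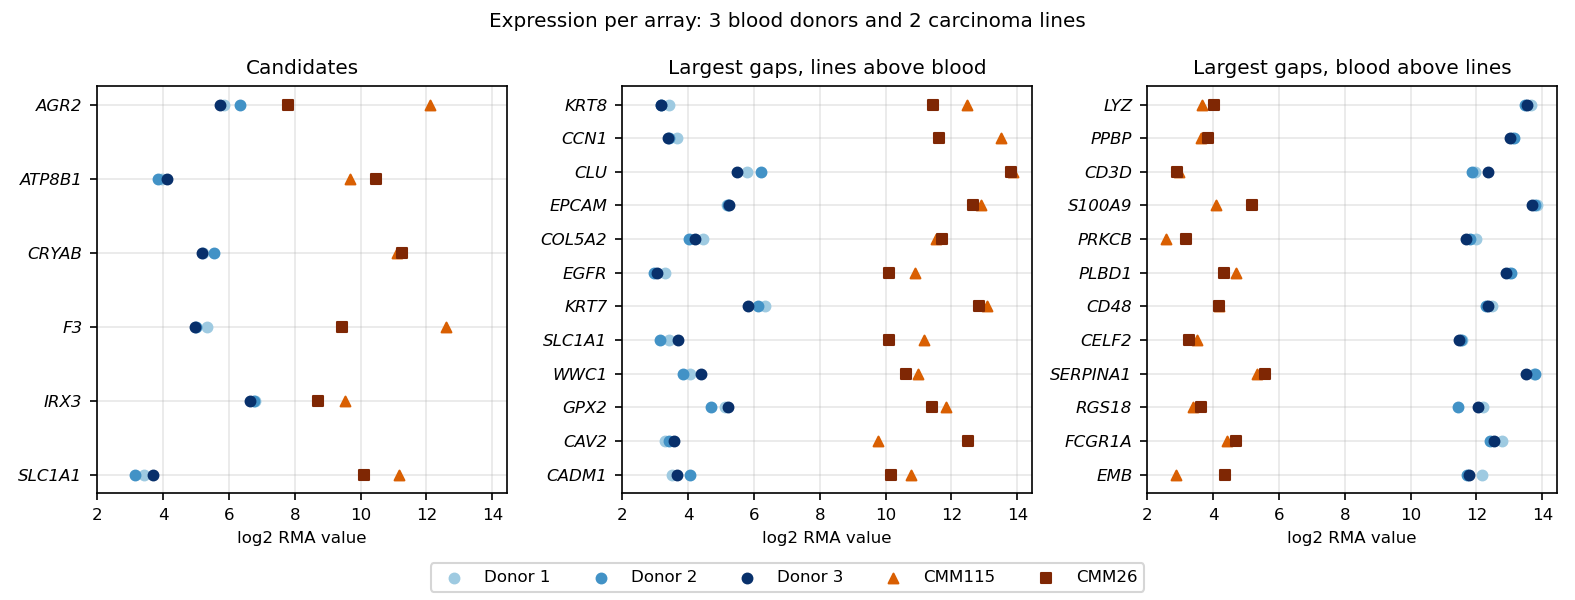
Log2 expression values (horizontal axis) of the 6 candidate markers and of the 12 genes with the widest gap in each direction, with 1 point per array for 3 blood donors (circles), CMM115 (triangles) and CMM26 (squares). The lines lie above all donors for all 6 candidates, with CMM26 nearest to the donors for AGR2 at 7.80 against a highest donor value of 6.32.

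The 6 genes taken here as the markers put forward by the study, recalled from its published work and not checked against it, are the secreted disulfide isomerase AGR2, the phospholipid transporter ATP8B1, the small heat shock protein CRYAB, the coagulation initiator tissue factor F3, the homeobox gene IRX3 and SLC1A1. Of these, 5 were higher in the lines past the threshold over all genes and 6 when adjusted over the list alone. The study is understood to have chosen these genes on these samples, so neither count is independent evidence of their direction. The log2 difference was 7.19 for SLC1A1 (SE 0.38, adjusted p = 0.00196), 6.10 for ATP8B1 (SE 0.27, adjusted p = 0.00142) and 5.88 for CRYAB (SE 0.15, adjusted p = 0.000522). F3 differed by 5.92 (SE 1.00, adjusted p = 0.026), with 12.59 in CMM115 and 9.44 in CMM26, and IRX3 by 2.38 (SE 0.26, adjusted p = 0.00997). The probe set that stands for AGR2 did not pass over all genes: it differed by 4.00 (SE 1.36, adjusted p = 0.132), with 12.10 in CMM115, 7.80 in CMM26 and a blood mean of 5.96 ± 0.32 (SD, n = 3). As a group the candidates were called higher by camera (adjusted p = 1.63e-05). The call was lost at an adjusted p = 0.144 with an estimated correlation.

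Of the other AGR2 probe sets, 1 passed (4.66, SE 0.97, adjusted p = 0.0435) and 1 did not (-0.18, adjusted p = 0.31), and the other F3 probe set passed (9.85, SE 0.56, adjusted p = 0.00234). The calls for AGR2, F3 and IRX3 changed when single arrays were left out and with the model. AGR2 passed with each line as its own group, a fit whose error comes from the donors alone and leaves out the difference between the lines. F3 and IRX3 missed with treat against 2-fold (adjusted p = 0.0762 and 0.0555). AGR2 passed without CMM26 (6.15, adjusted p = 0.015) and missed without CMM115 (1.85, adjusted p = 0.0678). F3 missed the threshold without donor 1, 2 or 3 (adjusted p = 0.117, 0.0925 and 0.098), and IRX3 missed it without donor 1 or 3 (adjusted p = 0.0678 and 0.051). The differences hardly moved in these fits, at 6.04, 5.87 and 5.85 for F3 and 2.42 and 2.34 for IRX3. Fewer arrays leave fewer degrees of freedom, so these misses do not point to a particular donor. SLC1A1, ATP8B1 and CRYAB passed under all 14 alternatives tried. Without donors 1, 2 and 3 in turn, 3, 4 and 3 candidates were past the threshold.

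Genes of epithelial junctions and identity were higher in the lines as a group. Of 32 measured, 27 were higher, 0 lower and 5 did not pass, and 27 were higher when adjusted over the list alone (median log2 difference 3.05, camera adjusted p = 2.5e-16; adjusted p = 0.128 with an estimated correlation). After EPCAM came the tight junction proteins TJP1 (6.06, SE 0.33; 0.97 and not past the threshold on its other probe set), CLDN7 (5.78) and OCLN (5.67), and the adherens junction cadherin CDH1 was higher by 3.25 (adjusted p = 0.0348). CRB3 (1.61, adjusted p = 0.211) and OVOL1 (0.38, adjusted p = 0.162) were among those that did not pass. Without donor 1 the count was 17.

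Keratins followed in part. Of 10 measured, KRT8, KRT7, KRT18 (4.53, adjusted p = 0.0104) and KRT80 (0.72, adjusted p = 0.0239) were higher, also when adjusted over the list alone, 0 were lower and 6 did not pass. KRT18 was not low in blood: it read 8.30, 8.80 and 7.99 in donors 1, 2 and 3, where the median of all values was 5.8. KRT17 read 9.64 in CMM115 and 4.35 in CMM26, whereas KRT13 read 6.30 and 9.87. The list was called higher (median 2.06, camera adjusted p = 0.00679; adjusted p = 0.20 with an estimated correlation). Without donor 1, 2 keratins remained past the threshold.

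Receptor tyrosine kinases and their ligands included 8 higher, 1 lower and 14 that did not pass, of 23. Adjusted over the list alone, 11 were higher and 1 lower. EGFR led, followed by the growth factor FGF2 (5.76, SE 0.20), its receptor FGFR2 (3.47) and the hepatocyte growth factor receptor MET (3.46). The MET ligand HGF was the 1 lower member (-0.83, adjusted p = 0.0055). IGF1R (1.13, adjusted p = 0.128) did not pass. The list was called higher (median 0.63, camera adjusted p = 0.00162; adjusted p = 0.151 with an estimated correlation). Without donor 1, 5 members were higher.

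Proliferation genes were higher in the lines. In the cell cycle and mitosis list 18 of 26 were higher, 0 lower and 8 did not pass, and 23 were higher when adjusted over the list alone (median 2.39, camera adjusted p = 5.35e-10; adjusted p = 0.297 with an estimated correlation). Cyclin D1, CCND1, differed most (4.16, SE 0.28, adjusted p = 0.00322), followed by the mitotic spindle proteins PRC1 (3.70), ASPM (3.51) and KIF23 (3.48, adjusted p = 0.0496). In the DNA replication list 9 of 28 were higher, 0 lower and 19 did not pass, with 21 higher when adjusted over the list alone. The origin licensing factor CDC6 was higher by 2.49, the ribonucleotide reductase subunit RRM1 by 1.92 and GINS1 by 1.83. RRM2 differed by 1.85 (adjusted p = 0.102). That list was called higher too (median 1.00, camera adjusted p = 2.53e-07; adjusted p = 0.285 with an estimated correlation). Without donor 1, donor 3, CMM115 or CMM26 in turn, 4, 13, 5 and 4 cell cycle genes and 1, 5, 1 and 2 replication genes were higher. Both lists also differed between the donors, as given in the comparison of donors.

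Of 18 cholesterol biosynthesis genes, 10 were higher in the lines, 1 was lower and 7 did not pass, with 11 higher and 1 lower when adjusted over the list alone (median 1.42, camera adjusted p = 4.59e-06; adjusted p = 0.20 with an estimated correlation). Squalene epoxidase, SQLE, was higher by 5.28 (SE 0.16, adjusted p = 0.000698), MSMO1 was higher by 4.35, CYP51A1 by 3.01 and the synthase HMGCS1 by 2.65. The lower member was the mevalonate pathway kinase PMVK (-0.93, adjusted p = 0.0215), and FDPS (1.38, adjusted p = 0.137) and INSIG1 (1.16, adjusted p = 0.175) did not pass. Without donor 1, 5 members were higher.

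All 25 pan-leukocyte genes were lower in the lines, also when adjusted over the list alone (median -5.29, camera adjusted p = 8.94e-19; adjusted p = 0.128 with an estimated correlation). The leukocyte phosphatase CD45, PTPRC, differed by -7.91, the adaptor TYROBP by -7.51 and ARHGDIB by -7.12. LCP1, the leukocyte plastin, read 3.92 in CMM115 and 8.32 in CMM26 against a blood mean of 13.20.

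T lymphocyte genes were lower for 20 of 23, with 0 higher and 3 that did not pass, and 22 were lower when adjusted over the list alone (median -3.55, camera adjusted p = 3.51e-13; adjusted p = 0.169 with an estimated correlation). The kinase LCK (-7.24), TRAT1 (-7.22) and CD3G (-6.09) followed CD3D, whereas CD8A (-3.19, adjusted p = 0.101) and TCF7 (-1.55, adjusted p = 0.145) did not pass. B lymphocyte genes were lower for 10 of 16, with 0 higher, 6 that did not pass and 11 lower when adjusted over the list alone (median -1.01, camera adjusted p = 1.43e-05; adjusted p = 0.20 with an estimated correlation). BANK1 (-4.91), the immunoglobulin joining chain JCHAIN (-4.58) and CD79B (-3.43), part of the B cell receptor, led. Cytotoxic and natural killer (NK) cell genes were lower for 7 of 19, with 0 higher and 12 that did not pass, and for 15 when adjusted over the list alone (median -3.36, camera adjusted p = 1.23e-06; adjusted p = 0.322 with an estimated correlation). Granzyme B, GZMB, differed by -7.12 (adjusted p = 0.0174) and the receptor KLRD1 by -6.67 (adjusted p = 0.0384), while GZMK differed by -4.15 (adjusted p = 0.0871) with values spread from 8.17 to 11.80 over the donors. Without donors 1, 2 and 3 in turn, 13, 19 and 15 T cell genes, 3, 8 and 7 B cell genes and 2, 9 and 7 cytotoxic genes were lower.

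Myeloid genes were lower as well. Of 24 neutrophil and granulocyte genes, 19 were lower, 0 higher and 5 did not pass, with 22 lower when adjusted over the list alone (median -4.13, camera adjusted p = 1.83e-12; adjusted p = 0.21 with an estimated correlation). The peptidylarginine deiminase PADI4 (-7.26), the bactericidal protein BPI (-7.22) and lactoferrin LTF (-6.85) stood behind S100A9, and MMP9 (-3.01, adjusted p = 0.0542) did not pass. Of 21 monocyte genes, 18 were lower, 0 higher and 3 did not pass, with 18 lower when adjusted over the list alone (median -3.99, camera adjusted p = 1.79e-11; adjusted p = 0.128 with an estimated correlation). The NADPH oxidase subunit CYBB (-6.73) and AIF1 (-6.54) came after LYZ and FCGR1A. Without donor 1, CMM115 or CMM26, 12, 13 and 12 neutrophil genes and 8, 9 and 9 monocyte genes were lower.

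The blood pellets also held platelet transcripts. Of 17 platelet and megakaryocyte genes, 13 were lower in the lines, 1 was higher and 3 did not pass, with 15 lower and 1 higher when adjusted over the list alone (median -2.54, camera adjusted p = 2.06e-08; adjusted p = 0.151 with an estimated correlation). RGS18, the coagulation factor F13A1 (-6.69) and P-selectin, SELP (-6.12), followed PPBP. The higher member was SPARC (3.23, adjusted p = 0.0358), a matrix protein that platelets share with many other cells. Without donors 1, 2 and 3 in turn, 8, 11 and 10 members were lower and 0, 0 and 1 higher. Of 14 erythroid genes 2 were higher, 1 was lower and 11 did not pass, counts that were equal over the list alone, and the list was not called (median -0.19, mean 0.14, camera adjusted p = 0.383). The heme synthesis enzyme ALAS2 was lower (-1.47, adjusted p = 0.00293), and the transferrin receptor TFRC (2.67) and the biliverdin reductase BLVRB (2.83), which are not confined to red cells, were higher. Without donor 1 or 3, 0 were higher, and without donor 2, CMM115 or CMM26, 1. Red cells had been lysed before RNA extraction, per the labels, and the globin genes have no named probe set here.

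The 12 genes of MHC class II presentation were lower in the lines for 7, with 0 higher and 5 that did not pass, and for 9 when adjusted over the list alone (median -4.06, camera adjusted p = 1.02e-05; adjusted p = 0.297 with an estimated correlation). The cathepsin CTSS (-6.20), also a monocyte gene, DLA-DQB1 (-6.12), DLA-DOB (-4.17) and DLA-DMA (-3.95) were lower. DLA-DRA (-6.13, adjusted p = 0.142) and DLA-DQA1 (-5.93, adjusted p = 0.0942) did not pass, with 10.80 and 9.09 in CMM115 and 3.88 and 3.57 in CMM26, while the other DLA-DQA1 probe set passed (adjusted p = 0.0391). Without donor 1, 2 or 3, 3 members each were lower.

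Immediate early and inflammatory genes were lower for 5 of 25, namely NFKBIA (-4.17), IL1B (-2.71), KLF4 (-2.48), ZFP36 (-2.10) and DUSP1 (-1.86), with 0 higher, 20 that did not pass and 5 lower over the list alone. The list was called lower (median -0.43, camera adjusted p = 0.00679; adjusted p = 0.408 with an estimated correlation). Without donors 1, 2 and 3 in turn, 0, 2 and 6 were lower. Endothelial genes were lower for 3 of 18, PECAM1 (-6.72), KDR (-2.03) and ESAM (-1.31), with 1 higher, 14 that did not pass and the equal counts over the list alone (median -0.17, camera adjusted p = 0.027; adjusted p = 0.22 with an estimated correlation). PECAM1 is carried by leukocytes and platelets too, and the higher member was the receptor FLT1 (5.51, adjusted p = 0.00161). Ribosomal protein genes were lower for 3 of 36, RPLP1 (-0.73), RPL13 (-0.42) and RPL34 (-0.34), with 0 higher, 33 that did not pass and 0 lower over the list alone (median -0.17, camera adjusted p = 0.0188; adjusted p = 0.285 with an estimated correlation). That call was also lost after quantile normalization (adjusted p = 0.0801), and without any of the 3 donors or CMM115 the count was 0.

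Besides the erythroid list, camera made no call in the main comparison for the following lists. In the mesenchymal and extracellular matrix list 4 genes were higher, 5 lower and 24 did not pass, of 33 (5 and 5 over the list alone). CCN1, COL5A2, CCN2 (4.51) and SPARC were higher, whereas fibronectin FN1 (-5.95), the transcription factors ZEB1 (-5.86) and ZEB2 (-4.48), TGFBI (-4.05) and THY1 (-2.17) were lower (median -0.07, mean 0.25, camera adjusted p = 0.50). Fry called the list lower (adjusted p = 0.00123). The median turned to 0.09 after centring on ribosomal proteins. Without donor 1, 2 genes of this list were higher and 3 lower, and without donor 2 the counts were the same. Of 21 mammary luminal and hormone response genes, the progesterone receptor PGR (5.02, SE 0.27, adjusted p = 0.0021) and ERBB3 (3.04) were higher and LTF, STAT5A (-2.34) and STAT5B (-1.41) lower, with 16 that did not pass (3 and 5 over the list alone; median -0.05, 0.12 after centring on ribosomal proteins; camera adjusted p = 0.50). LTF is also a neutrophil granule protein. The oestrogen receptor ESR1 differed by 0.01 (adjusted p = 0.964) and ERBB2 by 0.63 (adjusted p = 0.0639). Without CMM115, 4 genes of the luminal list were higher.

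Focal adhesion and integrin genes were higher for 8 of 21 and lower for 4, with 9 that did not pass (9 and 4 over the list alone; median 0.70, camera adjusted p = 0.0594). CAV2 and the integrin ITGA2 (3.85) were higher, and ITGA5 (-3.80), talin TLN1 (-3.25), ZYX (-2.26) and FLNA (-1.06) lower. Without donors 1, 2 and 3 only 1, 3 and 1 were higher and 0, 1 and 2 lower, without CMM115 and CMM26 2 and 0 were lower, and camera called the list without donor 2 (adjusted p = 0.0489), CMM115 (adjusted p = 0.0442) or CMM26 (adjusted p = 0.0101). With all arrays it was called with each line as its own group (adjusted p = 0.0158), with probe sets averaged (adjusted p = 0.0391) and by fry (adjusted p = 0.0173), but not with an estimated correlation (adjusted p = 0.285). Among 19 glycolysis genes the glucose transporter SLC2A1 (3.03, adjusted p = 0.00109), HK1 (1.46) and ENO1 (0.95) were higher and ENO2 (-1.75) and GAPDH (-0.85) lower, with 14 that did not pass (3 and 2 over the list alone). Its median was -0.03, which turned to 0.01 after median centring and 0.13 after centring on ribosomal proteins, and its mean 0.22 with a test pointing up (camera adjusted p = 0.627). Without donor 1, donor 3, CMM115 or CMM26, 1 glycolysis gene was higher and 1 lower, and without donor 2, 1 was lower.

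Myoepithelial and smooth muscle genes held 1 that passed, the tropomyosin TPM1 (1.85, adjusted p = 0.032), with 0 over the list alone and 14 of 15 that did not pass (median 0.56, camera adjusted p = 0.91). Without donor 1, donor 3 or CMM115, 0 members were higher; without CMM115, 2 were lower, and without CMM26, 4 were higher. Interferon-stimulated genes were higher for OAS2 (2.01, adjusted p = 0.0232) and lower for MX2 (-3.29), XAF1 (-1.88) and STAT2 (-0.54), with 17 of 21 that did not pass and the equal counts over the list alone. Without donor 1 or 3, 0 members were higher and 1 lower, without donor 2, 1 was lower, without CMM115, 0 were higher, and without CMM26, 3 were. The median was 0.61 and camera gave an adjusted p = 0.86. The 2 lines differed in this list, as given in the next comparison. CCN2, TGFBI, THY1, ZEB2, STAT5B, ESR1, ERBB2, HGF, ZYX, FLNA, PMVK, GAPDH and DUSP1 were named after their values were seen, to complete short counts or as known mammary genes. All 251 list members past the threshold kept their sign under median centring, quantile normalization and centring on ribosomal proteins, and 248, 247 and 244 of them stayed past it. These scalings moved the lines against blood by a median of only 0.040, 0.022 and 0.166 log2 units, so they could hardly have turned a sign.

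**Figure D2:**
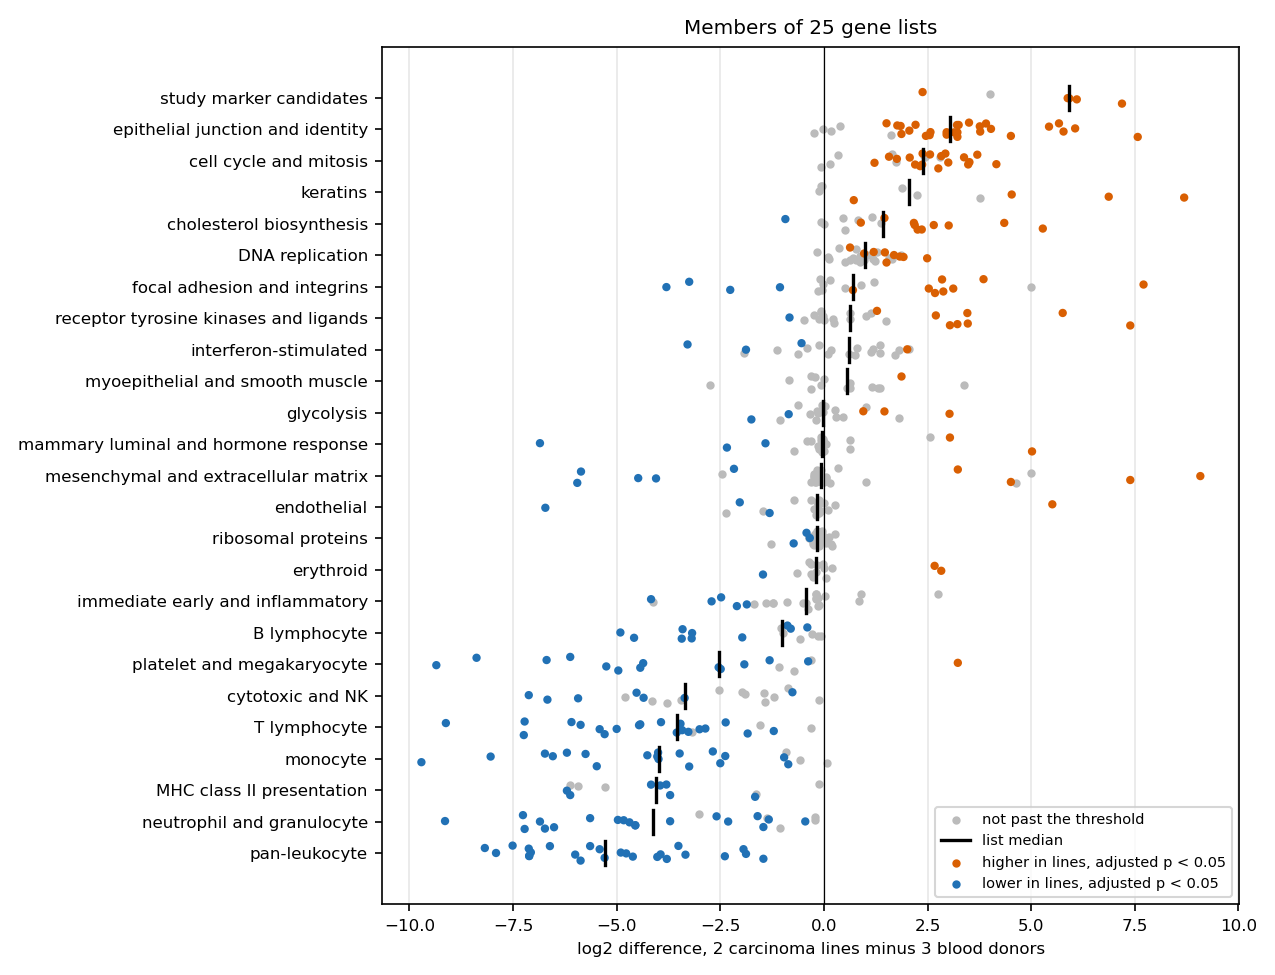
Log2 difference, lines minus blood (horizontal axis), of each measured member of 25 gene lists, with members past an adjusted p of 0.05 in orange (higher in the lines) or blue (lower) and list medians as black bars. Medians run from -5.29 for the pan-leukocyte genes to 5.90 for the candidates.

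The second comparison set CMM115 against CMM26. With 1 array per line there is no test and no p-value, and the values describe these arrays. CMM115 carried far more transcript of the antigen presentation genes HLA-DRB1 (11.30 against 4.30) and DLA-DRA (10.80 against 3.88). It also exceeded CMM26 in the alkaline phosphatase ALPL (13.26 against 5.54), the retinal dehydrogenase ALDH1A1 (12.38 against 4.67) and the contractile genes TPM2 (12.77 against 5.68) and MYLK (11.81 against 5.03). CMM26 exceeded CMM115 in the neutrophil-attracting chemokine CXCL8 (11.94 against 3.85), involucrin IVL, a component of the cornified envelope (11.81 against 3.77), and S100P (12.52 against 5.20).

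At least 2-fold apart were 3273 probe sets, 1928 higher in CMM115 and 1345 higher in CMM26. The corresponding counts were 1213 between donors 1 and 2, 531 between donors 1 and 3 and 2536 between donors 2 and 3. The other genes with the largest differences were PKIA (7.52), RTN1 (7.28), GSPT2 (6.61) and MGST1 (6.52) on the CMM115 side. On the CMM26 side they were LOC482175 (-7.52), LOC611685 (-6.15), the protease TMPRSS11D (-5.70), ERAS (-5.33), the peptidase DPP4 (-5.28), EGFLAM (-5.17) and CLIC3 (-4.67).

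Set against 10000 random lists of equal size matched on mean expression, 9 of the 26 list medians fell outside the central 95%. The genes of the random lists were drawn independently, so lists whose genes move together leave this range more easily. The MHC class II list lay highest in CMM115 (median difference 1.71; random lists -0.35 to 0.26), with 8 of 12 genes at least 2-fold higher there and 0 in CMM26. Interferon-stimulated genes followed (1.57; random lists -0.25 to 0.15), with 14 of 21 at least 2-fold higher in CMM115 and 1 in CMM26. RSAD2 differed by 4.90, ISG15 by 4.22 and IFI44L by 4.01. The myoepithelial and smooth muscle list differed by 1.01 (random lists -0.23 to 0.14), with TPM2 at 7.09, MYLK at 6.77 and the myosin light chain MYL9 at 4.56. The candidate markers differed by 0.93 (random lists -0.42 to 0.43), chiefly AGR2 (4.30), F3 (3.14) and SLC1A1 (1.06). A list the study chose on these samples is not independent evidence here either.

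Smaller shifts towards CMM115 appeared in the lists of focal adhesion (0.34), cholesterol biosynthesis (0.30), epithelial junctions (0.22) and receptor tyrosine kinases (0.12). Within them CAV1 (-4.49) and CAV2 (-2.73) went the other way, ITGA2 was higher in CMM115 by 1.80, CDH1 by 1.94, CRB3 by 2.22, SREBF2 by 0.94 and EREG by 1.49, and AREG differed by -1.23. Pan-leukocyte genes shifted towards CMM26 (-0.33; random lists -0.27 to 0.16), with LCP1 at -4.40, CORO1A at -1.87 and EVI2B at -1.86. The medians of the cell cycle list (-0.02), the DNA replication list (0.12) and the keratins (0.06) lay within the range of the random lists. Under the 3 other scalings the lowest class II median was 1.65, and the lowest interferon median 1.5, both after quantile normalization.

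**Figure D3:**
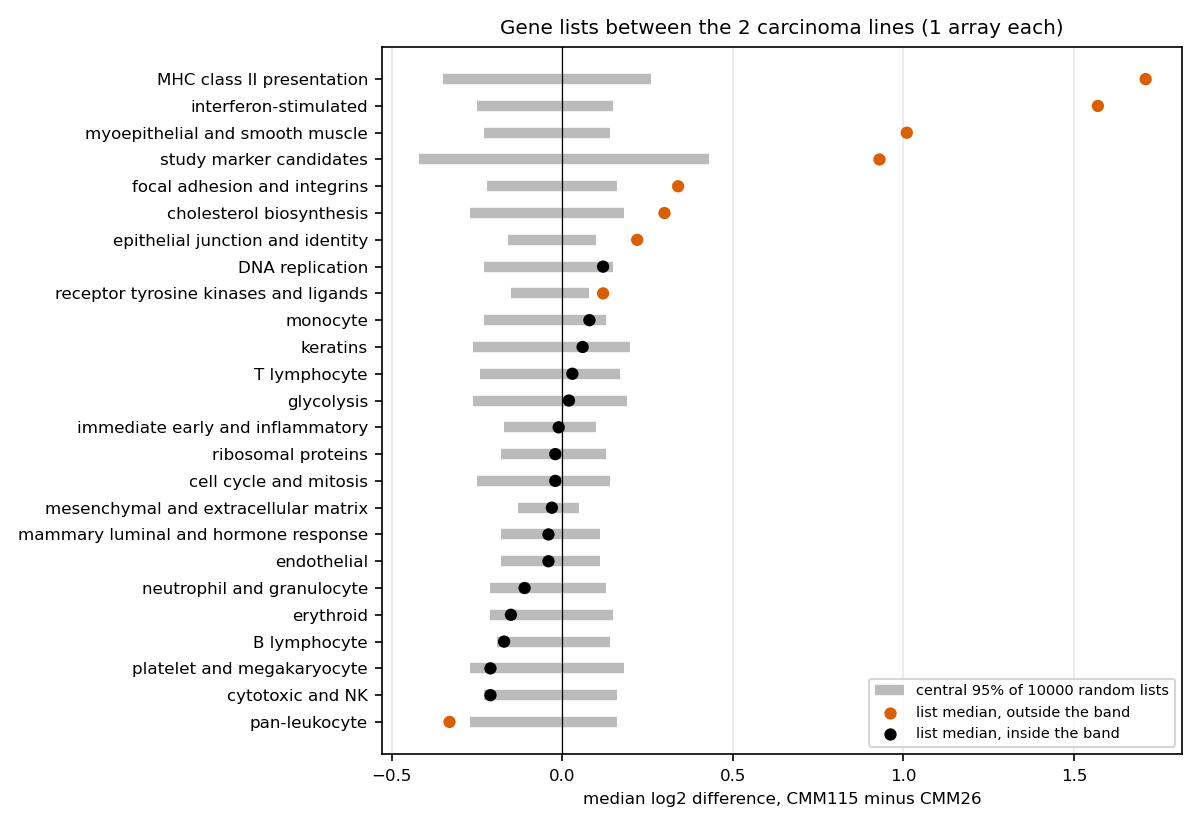
Median log2 difference, CMM115 minus CMM26 (horizontal axis), of 25 gene lists as points, over grey bars for the central 95% of 10000 matched random lists. The points of 9 lists lie outside their bars, from -0.33 for pan-leukocyte genes to 1.71 for MHC class II presentation.

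The third comparison asked how far the 3 healthy donors differed among themselves, which sets the background for any marker in blood. The sample name of donor 3 has another form than those of donors 1 and 2, and the labels do not say what this stands for. They differed most in cytotoxic lymphocyte genes. CXCR6, a chemokine receptor of such cells, read 7.90, 4.06 and 9.47 in donors 1, 2 and 3, the NK receptor KLRD1 10.40, 7.64 and 11.77, the chemokine CCL4 8.93, 6.66 and 10.64 and granzyme A, GZMA, 10.21, 8.18 and 11.82. No test was made between single donors. GBP6 (range 4.29), GLCCI1 (3.90), MPP5 (3.82) and GZMK (3.63) were the others among the 8 widest ranges.

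In the cytotoxic and NK list the median deviation from the donor mean was -0.12, -0.84 and 1.12 in donors 1, 2 and 3, and 9 of 19 genes spanned at least 2 log2 units. T lymphocyte genes deviated by 0.04, -0.22 and 0.31, with CD8A spanning 3.04, SH2D1A 2.94 and CD8B 2.31. B lymphocyte genes went the other way (-0.06, 0.30 and -0.30), with EBF1 at 7.00, 8.12 and 5.88, as did neutrophil genes (0.13, 0.26 and -0.40), with MMP9 at 7.94, 9.12 and 6.94. So did platelet genes (-0.06, 0.29 and -0.30) and immediate early genes (0.19 and -0.40 in donors 2 and 3). Pan-leukocyte genes deviated by 0.00, 0.11 and -0.03. Cell cycle genes deviated by 0.04, -0.58 and 0.46, with BUB1B spanning 2.55, KIF23 2.41 and TTK 2.31, and DNA replication genes by 0.00, -0.38 and 0.32. Interferon-stimulated genes deviated by 0.19, -0.56 and 0.35, with IFI44 spanning 2.71 and ISG15 2.67, and TNFAIP3 of the inflammatory list spanned 2.14. Donor 2 had the highest poly-A controls, at 10.09, and the lowest correlation between donors was that of donors 2 and 3, at 0.976. The 6 candidate markers spanned at most 0.61 log2 units over the donors, for AGR2.

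**Figure D4:**
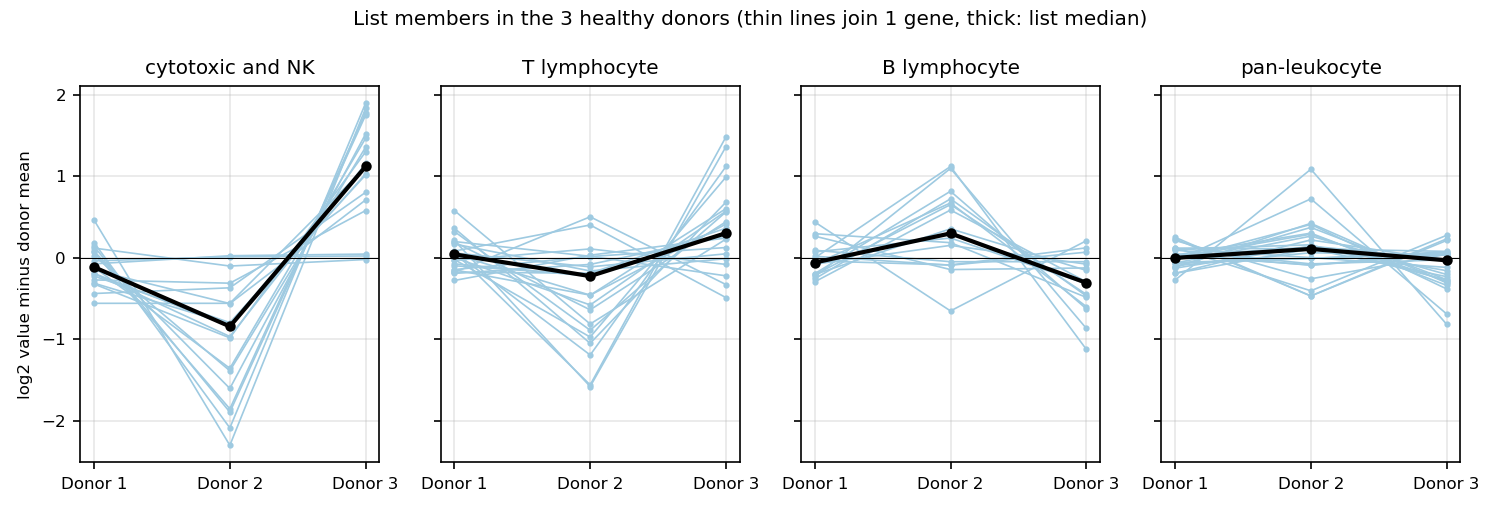
Log2 value minus the mean of the 3 donors (vertical axis) for each gene of 4 lists in donors 1, 2 and 3, with the list median as the thick line. The median of the cytotoxic and NK list runs from -0.84 in donor 2 to 1.12 in donor 3, that of the pan-leukocyte list from -0.03 to 0.11.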

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

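The tests in this part were chosen after the results were seen. In 4 of the named genes the lines lay on opposite sides of all 3 donors, each at least 2-fold from the donor mean, a difference in direction that was not tested. ALDH1A1 differed between CMM115 and CMM26 by 7.71 log2 units (12.38 and 4.67, donors 6.26 to 6.41). PKIA differed by 7.52 (11.16 and 3.64, donors 5.31 to 6.73), MYLK by 6.77 (11.81 and 5.03, donors 7.31 to 8.13) and IFI44L by 4.01 (10.41 and 6.40, donors 8.31 to 9.53). CALD1, a list member noticed after its values were seen, did so as well (12.25 and 8.09, donors 9.55 to 9.68). Each value rests on 1 array per line.

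MHC class II genes were higher in CMM115 than in CMM26 by a median of 1.71. Leukocytes in the CMM115 sample would bring their abundant transcripts, but 12 pan-leukocyte genes with a blood mean of at least 11 lay at a median of -7.36 against blood (upper quartile -6.29), while the class II median was -2.73. The highest of the 12, LAPTM5, lay at -2.00. Under 3 other scalings the lowest class II difference was 1.65. The deposited arrays already shared one distribution, so rescaling could hardly have moved this value, and it does not decide on scaling. An interferon gamma type response in CMM115 may contribute: a list of 16 such genes differed by 1.38 (upper bound of the random lists 0.19). Of these, 10 were at least 2-fold higher in CMM115, with PSMB8 at 5.14, GBP1 at 4.34 and TAP1 at 2.72, and 0 in CMM26. CXCL10 (0.17), ICAM1 (0.13), NLRC5 (-0.21), SOCS1 (-0.33) and WARS1 (-0.46) differed by less than 2-fold. Such a response stays open: the probe set of CIITA, the class II transactivator, read between 7.47 and 7.70 on all 5 arrays, blood included, and so carries no information. The interferon-stimulated list differed too, by 1.57, so the type of response is not separated. A difference between the tumours the lines came from was not tested and stays open too.

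Cytotoxic and NK genes differed between donors 3 and 2 by a median of 1.92. A different share of all T cells as the only cause is argued against by 21 T cell genes other than CD8A and CD8B, at a median of 0.52 (upper quartile 1.08). A contribution from such a share stays open, because these genes were also higher in donor 3 at the median. Lower RNA integrity in donor 2 would raise its 3′ minus 5′ values, and is argued against because these were lower in donor 2 than in donor 3 for 5 of 6 control pairs and higher only for an actin pair, by 0.27. The pairs are not independent, since some actin pairs share a 3′ probe set. The EF1A pair sets a bright 3′ probe set against a dim 5′ one (13.7 and 6.24 in donor 2). Less messenger RNA in the donor 2 reaction stays open: it was not tested, since normalised values do not show it, and its poly-A controls read 10.09 against 8.60 in donor 3. A larger share of CD8 and NK type cells in donor 3 may underlie the pattern, with CD8A at 3.04 and CD8B at 2.31. It stays open because CD4, which was to differ by less than 0.5, differed by -0.90, and because no cell counts were available. CD4 may not stand for T cells alone here, so its value does not decide the question. It read 11.36, 11.68 and 10.79 in donors 1, 2 and 3, a course like that of the neutrophil list and unlike that of the T lymphocyte list.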

How the results depend on the processing

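The counts of list members without each array and the scaling of line differences were tests chosen after the results were seen. Among 107 named genes past the threshold, 0 reversed under any alternative. From 64 to 85 stayed past it when 1 array was left out, 87 with each line as its own group, 69 with treat and from 101 to 106 under the others.

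Leaving out 1 array gave between 1218 and 3420 probe sets higher and between 1120 and 2538 lower, 470 to 1399 genes higher and 445 to 1003 lower, 7 to 11 lists higher and 11 to 13 lower, and 505 to 807 probe sets with a gap of at least 8-fold with the lines above and 611 to 737 with blood above, against 488 and 603 with all arrays. Fewer arrays leave fewer degrees of freedom. Against 2-fold, treat gave 1053 probe sets higher and 1006 lower, and 409 and 415 genes. Probe sets with a gap numbered 1031 with the lines above and 1037 with blood above at 4-fold, 488 and 603 at 8-fold and 241 and 375 at 16-fold. At 4-fold, 814 probe sets differed between the lines and on average 125 between donors. With an estimated correlation 0 lists were called higher and 0 lower. The other 84 counts stayed within 1.5 times.

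Without CMM115, KRT17 turned to -0.41, TPM2 to -0.16 and RSAD2 to -0.39. They were 4.88, 6.94 and 4.51 without CMM26. The myoepithelial list turned to -0.24 (adjusted p = 0.0442) and the interferon list to -0.39 (adjusted p = 0.0391) without CMM115, against 1.48 (adjusted p = 0.0256) and 1.87 (adjusted p = 0.0264) without CMM26. For both lists the remaining line sets the direction. The test, but not the median, also turned to lower for the myoepithelial list after centring on ribosomal proteins (0.72, adjusted p = 0.892). The interferon list did so with fry (0.61, adjusted p = 0.763), without donor 2 (0.10, adjusted p = 0.968), after median centring (0.65, adjusted p = 0.988) and after centring on ribosomal proteins (0.77, adjusted p = 0.584); the cause was not tested. Of the other list results 323 were the same, 12 gained a call and 22 lost one. The ribosomal list lost its call with quantile normalization (adjusted p = 0.0801) and with centring on itself (adjusted p = 0.277), the endothelial list with probe sets averaged (adjusted p = 0.0518) and the immediate early list with fry (adjusted p = 0.0619).

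No paired analysis was possible because donors and lines share no source. Without detection calls, signal over background could not be judged for dim probe sets.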

Other observations

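The tests of the squamous list and of the lists and genes above were chosen after the results were seen, and the values of KRT13, GBP5, CD8A and CD8B were known before their tests. Some genes outside the lists fixed beforehand were high in both lines, chosen here after their values were seen: S100A14 read 11.50 and 12.23 in CMM115 and CMM26 and between 5.90 and 5.97 in the donors, and DSG3 read 9.77 and 11.51 against 4.09 to 4.54. IDO1 read 8.35 and 6.85 against 4.42 to 4.72.

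IVL was 8.03 log2 units higher in CMM26, and a squamous differentiation programme in that line is a candidate explanation. The other 24 genes of a squamous list had a median CMM115 minus CMM26 difference of -0.13, at the 4.0th percentile of matched random lists, whose 2.5th percentile was -0.15. KRT13 (-3.58), DSG3 (-1.74) and TGM1 (-1.10) were higher in CMM26, and KLK6 (3.92) was higher in CMM115. The median lay short of the bound, and members went both ways, so the explanation stays open. That a value this near the bound leaves it open was decided after the value was seen.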
